A study of Mus musculus with 4 samples.

How the data were processed

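Small RNA libraries of the main olfactory epithelium of 4 male C57BL/6 mouse samples 3 months of age were compared, 2 wild type and 2 AC3-/-, grouped by their sample titles. Per the labels' protocols, the tissue was frozen, RNA was extracted with Trizol, and libraries were made with a kit that ligates adaptors to both ends of small RNAs, amplifies them by PCR, and selects them by length on a gel, before sequencing. Ligation and PCR favour some sequences, so levels of different miRNAs are not comparable as molecule numbers, while the same miRNA can be compared between libraries. No molecular identifiers are described, so reads are not independent molecules, and read numbers cover counting error only.

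The authors deposited 1 comparison table of 1167 miRNAs. The submitters' processing notes name Bowtie, DESeq 1.8.3 and the GRCm38 build, with no role or order; the read counter, the miRBase release and the filters are not given in the sources used here. The 2 abundance columns of the authors' deposited table hold a signal, the mean of the normalised read counts of each genotype, per the file headers and the values, and not raw counts. The table also holds the authors' log2 fold change of AC3-/- over wild type, and the authors' p-value and adjusted p-value. The log2 fold change in the authors' deposited table is shrunken toward 0: for miRNAs with a mean of at least 100 it kept a median of 86.1% of the log2 ratio of the deposited means. The adjusted p equals the Benjamini-Hochberg adjustment over all 1167 rows, and the authors' mark of significance equals an unadjusted p under 0.05 in all 1167. No per-sample columns were left unused.

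As fixed before the data were examined, the main result for single miRNAs is the authors' deposited table, tallied at an adjusted p of 0.05 with no further test. miRNAs were named by a rule fixed then too: among those past the threshold, the 10 largest changes in each direction with a value of at least 10 in the higher genotype, or the 5 smallest p-values where none passed in a direction; the 5 most abundant called miRNAs per direction; the 10 most abundant miRNAs; and up to 4 most abundant members of each list. This rule took 83 miRNAs, and the text gives those that its comparisons rest on. miR-124-5p, miR-124b-3p, miR-183-3p, miR-200b-5p, miR-155-5p, miR-129-5p, miR-1298-5p, miR-18a-5p, miR-489-3p and miR-344-3p fall outside the rule and were chosen after their values were seen.

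20 lists of miRNAs (families, clusters, and markers of cell types that the tissue sample could hold) were also fixed before the data were examined. A list's median log2 fold change was compared with 10000 random lists of the same size matched on 20 bins of abundance, as a description of these libraries. As planned, members past the adjusted p of 0.05 were compared inside and outside each list by Fisher's exact test. Both used Benjamini-Hochberg adjustment over the lists. No list had an adjusted Fisher p under 0.84 in this planned test. The same test on members with an unadjusted p under 0.05, adjusted alike, was not in the plan. On simulated values, independent between miRNAs, the list of the Dlk1-Dio3 miRNA cluster, with 78 rows, was shifted by 0.3 on the log2 scale. It was called in 5 of 5 runs and other lists in 1 of 85 tests. The other lists are smaller and members of a list can move together, so these rates do not carry over to such lists.

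The whole reads of each library were recovered after the table was seen. Each deposited mean is a whole-number combination of 2 steps, the normalised values of 1 read in the 2 libraries, so most means have 1 solution. For AC3-/- 1123 of 1167 rows (96.2%) and for wild type 1128 (96.7%) had 1 solution, including every row under 10000; the most abundant miRNAs had several and were left without library values. Size factors were 1.148 and 1.099 for AC3-/- libraries a and b and 0.9411 and 0.8551 for wild-type libraries a and b. The letters carry no replicate number. In simulated tables all 1109 and 1126 rows with 1 solution were right. Differences between recovered libraries were tested with limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(normalised value + 1) over 447 miRNAs with a mean of at least 10; adding 1 understates the change of low miRNAs. In libraries simulated with 1 dispersion of 0.126 for every miRNA and library, limma called 54 of 86 miRNAs changed 4-fold and 3 unchanged ones among 461 tested. The measured spread was uneven. The SD of the log2 ratio was 1.11 between the wild-type libraries and 0.57 between the AC3-/- libraries, so these rates may not hold for the data. 19 lists with at least 3 of these 447 miRNAs were also tested with limma's camera, with a preset correlation of 0.01 and with an estimated one, and with limma's fry. In 5 simulated runs with independent miRNAs and the 43 of the Dlk1-Dio3 list shifted by 1 on the log2 scale, they called the shifted list 5, 0 and 4 times and other lists 0, 0 and 2 times in 85 tests. With either possible pairing of the recovered libraries as a block, limma called 79 of 80 simulated miRNAs shifted by 2 on the log2 scale, and 3 and 6 unchanged ones, with 447 simulated. The camera, fry and block simulations used 1 spread for every miRNA, so the same limit applies. Fold changes of library values are ratios of means with 1 added.

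Rows with nearly equal reads in every library, within 3 reads or 5% at a mean of at least 50, were taken as sharing reads. Where library values were lacking, as for miR-9-5p and miR-9b-3p, the genotype means had to be nearly equal instead. This gave 16 pairs, whose rows were kept in the list medians and list tests. Coordinates are from GENCODE M21 on GRCm38. Alternatives planned before the data were examined were other thresholds, abundance minimums, recentring, pseudocounts of 1 and 10, and other list statistics; the limma fits, also with no minimum and after quantile normalisation, camera, fry and replicate blocks on recovered libraries, leaving out each recovered library and scaling to totals were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.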

Results

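Small RNA was sequenced from the main olfactory epithelium, the sheet of sensory neurons and supporting cells that lines the back of the nose, of male C57BL/6 mice 3 months of age. 2 libraries came from wild-type mice and 2 from mice lacking adenylyl cyclase 3 (AC3), the enzyme that makes cAMP in olfactory sensory neurons when an odour receptor is activated. The comparison asks how the miRNA profile of this tissue differs when that signalling enzyme is missing. AC3 is encoded by Adcy3, which lies on chromosome 12 from 4133103 to 4213525 on the plus strand (GRCm38); its mRNA is not measured in small RNA libraries, so the genotype was not checked in these data. The authors' deposited table lists 1167 miRNAs, of which 1123 carry miRBase-style mouse names and 44 are candidate miRNAs, with a mean normalised read count per genotype. The means summed to 8739148 in AC3-/- and 12320877 in wild type, which stand for 19201686 to 20063529 reads in the 2 AC3-/- libraries together and 21071945 to 23190561 reads in the 2 wild-type libraries. The labels do not say that the libraries of a genotype came from separate mice, so p-values measure only the spread between these libraries, which may be technical.

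miR-124-3p, a miRNA known to be abundant in neurons, had a higher mean in the AC3-/- libraries. The authors' deposited table gives it a mean normalised read count of 205.6 in AC3-/- and 29.34 in wild type, 7.01-fold higher, with a shrunken log2 fold change of 2.26, p = 1.37e-08 and an adjusted p of 1.59e-05 over all 1167 miRNAs. The values of the single libraries, worked back from the deposited means, were 228.2 and 183.0 in AC3-/- libraries a and b and 21.25 and 37.42 in wild-type libraries a and b (262, 201, 20 and 32 reads). The genes of miR-124 lie at 3 places in GRCm38: Mir124a-1 on chromosome 14 from 64590657 to 64590741, in an exon of the noncoding host gene Mir124a-1hg; Mir124a-2 on chromosome 3 from 17795662 to 17795770, in an exon of Mir124-2hg; and Mir124a-3 on chromosome 2 from 180894040 to 180894107, outside any annotated gene on its strand. The mature miRNA does not tell them apart. A limma fit to the recovered libraries gave a log2 difference of 2.81 with a standard error of 0.41 and ranked miR-124-3p 1 of 447 by p, but with an adjusted p of 0.328 it did not pass, and no miRNA did. With 1 library left out the log2 difference stayed between 2.42 and 3.21, while the adjusted p followed the pair that then gives all of the spread. It was 0.999 and 0.993 without AC3-/- library a or b (log2 differences of 2.65 and 2.97, spread from the wild-type pair), and 0.000142 and 0.000113 without wild-type library a or b (2.42 and 3.21, spread from the AC3-/- pair). 2 low-level relatives, named after their values were seen, lay in the same direction without passing: the authors' deposited table gives miR-124-5p means of 13.28 and 3.295 (adjusted p = 0.9395) and miR-124b-3p means of 12.85 and 2.763 (adjusted p = 0.9395). Their reads per library were nearly equal, 19, 11, 4 and 2 for miR-124-5p against 18, 11, 3 and 2 for miR-124b-3p, so they were not counted as separate observations.

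Beyond miR-124-3p, no miRNA passed the adjusted p of 0.05, and the next smallest adjusted p in the authors' deposited table was 0.9254. An unadjusted p under 0.05 was given in the authors' deposited table to 41 miRNAs, 18 higher and 23 lower in AC3-/-, where 58.4 would be expected by chance; the column that marks miRNAs as significant in the authors' deposited table marks exactly these 41. The shortfall against chance lay in rows with a mean under 10, which hold 12 of the 41. With a mean of at least 10, 29 of 492 miRNAs had such a p, and with at least 100, 17 of 296, a share slightly above 0.05 in each. The limma fit over 447 miRNAs gave 18 with an unadjusted p under 0.05, against 22.4 expected, and none past the adjusted threshold. Without wild-type library a it gave 65 past it, with the lone wild-type library assumed to vary like the AC3-/- pair, and without wild-type library b 1, miR-124-3p. An exact permutation test of 2 libraries against 2 cannot go below p = 0.333.

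**Figure D1:**
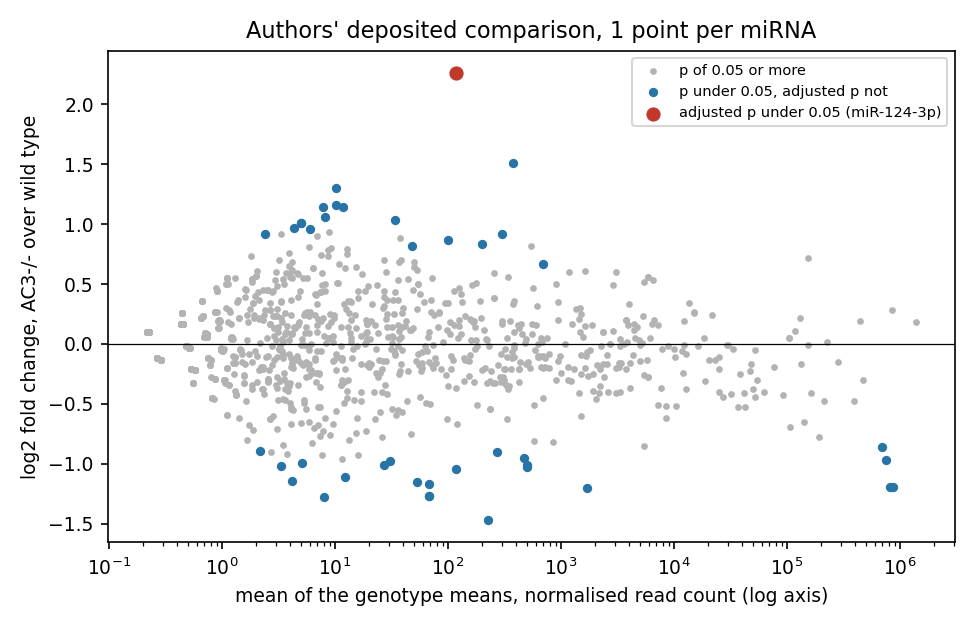
The log2 fold change of AC3-/- over wild type (vertical axis) against the mean of the genotype means in normalised read counts (horizontal log axis), both from the authors' deposited table, 1 point per miRNA. miR-124-3p, at 2.26, is the 1 miRNA with an adjusted p under 0.05, and 41 miRNAs, this one included, have an unadjusted p under 0.05.

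The sensory-organ cluster miR-183/96/182 and the miR-200 family, both abundant in sensory epithelia, were lower in the AC3-/- means as lists, and no member passed the adjusted p. All 6 miR-183 cluster miRNAs and all 10 miR-200 family miRNAs lay below 0 in the authors' deposited table, with median log2 fold changes of -0.89 and -0.54. Against 10000 random lists matched on abundance, the share of random lists at least as far out, two-sided and adjusted over 20 lists, was 0.004 for each; it is called the adjusted share from here on. limma's camera, on the 3 miR-183 cluster and 4 miR-200 family miRNAs among 447 with library values, called neither: adjusted p = 0.0591 and 0.266 over 19 lists with a preset correlation of 0.01, and adjusted p = 0.99 for each with an estimated correlation. In simulated libraries camera with an estimated correlation called a list shifted by 1 on the log2 scale in 0 of 5 runs, so its lack of a call says little. The miR-183 cluster held 9.37% of the AC3-/- total and 22.0% of the wild-type total, and the miR-200 family 11.6% and 22.3%. In the authors' deposited table miR-183-5p had means of 322736 in AC3-/- and 1304447 in wild type (log2 fold change -1.19, p = 0.0163), miR-182-5p 386391 and 1130689 (-0.97, p = 0.0465), miR-200b-3p 399796 and 1351262 (-1.19, p = 0.0115) and miR-200a-3p 398861 and 997135 (-0.86, p = 0.0242). 3 of the 6 miR-183 cluster miRNAs had an unadjusted p under 0.05 in the authors' deposited table (Fisher's exact test, not in the plan, adjusted p = 0.015 over 20 lists). This test takes members as independent, which these are not: 2 of the 3, miR-182-5p and miR-182-3p, are arms of 1 precursor. Mir183, Mir96 and Mir182 lie on the minus strand of chromosome 6, at 30169668 to 30169737, 30169446 to 30169551 and 30165918 to 30165992, outside annotated genes on that strand; Mir200b and Mir200a lie on the minus strand of chromosome 4, at 156055681 to 156055750 and 156054896 to 156054985, in an intron of Ttll10 (GRCm38).

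Where library values could be recovered, this difference rested on 1 wild-type library. miR-182-3p had 956.3 normalised reads in wild-type library a and 4671.8 in library b, against 879.0 and 365.0 in the AC3-/- libraries. miR-183-3p had 272.0 and 1410.3 in wild type against 399.0 and 225.7, and miR-200b-5p 3783.8 and 11471.9 against 3296.4 and 3306.9. Over the cluster's 3 miRNAs with library values and a mean of at least 10, the median log2 ratio of the AC3-/- mean was -0.11 to wild-type library a and -2.17 to library b, and over the miR-200 family's 4 it was 0.35 and -0.91. Without library b the miR-200 median over its 5 miRNAs with library values was 0.22, of the opposite sign, and the adjusted shares were 0.554 for the miR-200 family and 0.98 for the miR-183 cluster. Over the same miRNAs with all 4 libraries the medians were -0.53 for the miR-200 family (5 miRNAs, adjusted share 0.176) and -1.43 for the miR-183 cluster (3 miRNAs, 0.102). These medians carry no shrinkage and are not near 0, so with so few miRNAs the adjusted share alone says little. The most abundant members, miR-183-5p and miR-200b-3p among them, could not be split into libraries. Counting only the more abundant arm of each precursor left 5 and 3 miRNAs in the authors' deposited table, with medians of -0.69 and -0.97 that were no smaller in size, and adjusted shares of 0.164 and 0.18.

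Wild-type library b differed from the other 3 across the profile. Over 447 miRNAs with library values and a mean of at least 10, 115 lay 2-fold or more apart between the wild-type libraries and 26 between the AC3-/- libraries, and the SD of the log2 ratio was 1.11 and 0.57. Wild-type library a lay closer to the AC3-/- libraries, with 42 and 52 miRNAs 2-fold apart, than to its own partner. The list of miR-34b, miR-34c and miR-449 miRNAs, made in multiciliated cells such as those of the airway lining, was lower in wild-type library b for all 6 miRNAs with library values, with a median log2 ratio to library a of -2.93. miR-449a-5p had 9078.7 normalised reads in wild-type library a and 512.2 in library b, with 4027.3 and 5969.4 in AC3-/-, and miR-34c-3p had 8739.7 and 1675.8 with 3579.5 and 6999.8. Between the genotype means of the authors' deposited table the log2 fold change was 0.03 for miR-449a-5p and the list median 0.05 (adjusted share 0.734).

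**Figure D2:**
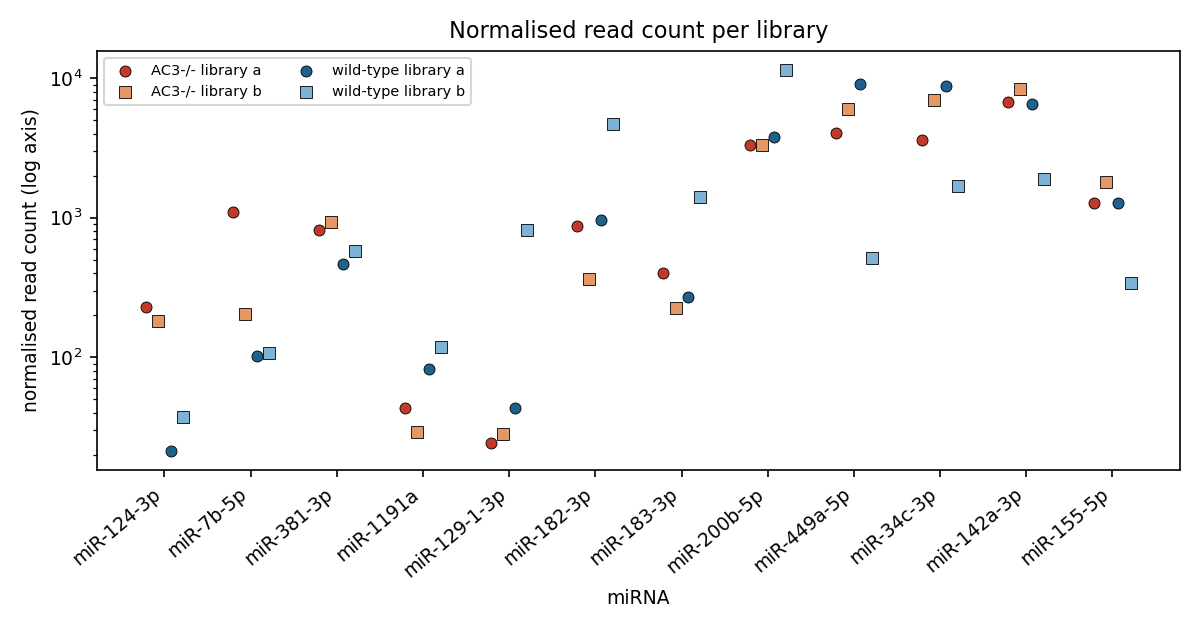
Normalised read count (vertical log axis) of 12 miRNAs (horizontal axis) in each of the 4 libraries, 1 marker per library, recovered from the authors' deposited means. miR-124-3p lies at 228.2 and 183.0 in AC3-/- and 21.25 and 37.42 in wild type, while miR-182-3p, miR-200b-5p and miR-449a-5p separate wild-type library b from the other 3 libraries.

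The leukocyte miRNAs lay higher in the AC3-/- means, and where library values could be recovered this too rested on wild-type library b. 14 of the list's 15 miRNAs were above 0 in the authors' deposited table, with a median log2 fold change of 0.29 and an adjusted share of 0.011. camera gave adjusted p = 0.0144 with a preset correlation and adjusted p = 0.99 with an estimated correlation. miR-142a-3p, made throughout the blood lineage, had 6699.1 and 8355.2 normalised reads in AC3-/- against 6565.7 and 1901.5 in wild type, and miR-155-5p, known for its part in activated immune cells, 1277.1 and 1798.7 against 1282.5 and 341.5. The list's median log2 ratio was -0.02 to wild-type library a and 1.63 to library b over 12 miRNAs. The most abundant member, miR-146a-5p, could not be split into libraries. Its means in the authors' deposited table were 201431 in AC3-/- and 105973 in wild type (log2 fold change 0.72, adjusted p = 0.9395). Without library b the adjusted share over the 14 miRNAs with library values was 0.991 with a median of -0.02, against 0.06 with a median of 0.37 with all 4 libraries. The authors' deposited table gives identical means to miR-142a-3p and miR-142b, so these 2 count the same reads.

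miRNAs of the imprinted Dlk1-Dio3 cluster on distal chromosome 12 lay slightly higher in AC3-/- as a list. 51 of 78 were above 0 in the authors' deposited table, with a median log2 fold change of 0.14 and an adjusted share of 0.011, and none passed the adjusted p. camera gave adjusted p = 0.0408 with a preset correlation and adjusted p = 0.99 with an estimated correlation, and limma's fry an adjusted p of 0.102. The median log2 ratio of the 43 with library values and a mean of at least 10 was 0.26 to each wild-type library and 0.21 to their mean. A mean of 2 libraries over 1 library leans upward where libraries vary, so the equal values are no separate support. Medians with 1 library left out lean likewise, upward without a wild-type library and downward without an AC3-/- one. miR-381-3p, from chromosome 12 at 109726822 to 109726896, had 818.9 and 937.6 normalised reads in AC3-/- against 464.3 and 578.9 in wild type (log2 fold change 0.67, p = 0.0276, adjusted p = 0.9395 in the authors' deposited table). miR-127-3p had 1931.3 and 1514.7 against 1684.2 and 1385.8, and miR-379-5p 767.5 and 1021.3 against 1052.0 and 939.0. With fewer members the median in the authors' deposited table stayed as high but the list no longer stood apart: 0.16 over 43 miRNAs of at least 10 normalised reads (adjusted share 0.0944), 0.15 over 13 of at least 100 (0.618) and 0.16 over 47 with the more abundant arm only (0.184). Over the 78 miRNAs with library values, the median log2 ratio was 0.21 (adjusted share 0.102). Left out in turn, AC3-/- libraries a and b gave 0.06 and 0.30 (adjusted shares 0.443 and 0.004). Wild-type libraries a and b gave 0.37 and 0.31 (0.208 and 0.521). Of these, the list stood apart without AC3-/- library b alone. Random lists take no account of members that move together, as those of 1 cluster or precursor can. The correlation that camera estimated between members was 0.99 for the miR-183 cluster, 0.93 for the miR-200 family and 0.57 for the leukocyte list, for which random lists, and Fisher's test, would understate chance. It was -0.022 over 43 miRNAs of the Dlk1-Dio3 list, which showed no such movement in these 4 libraries.

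**Figure D3:**
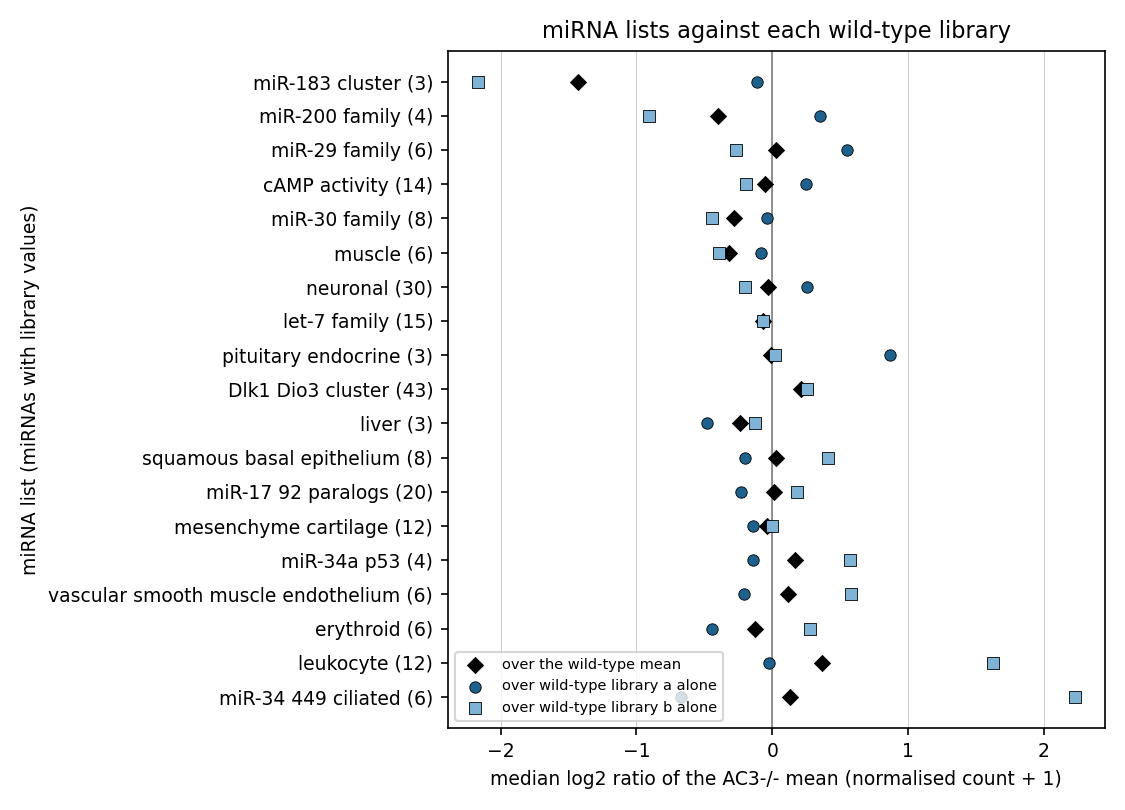
Median log2 ratio (horizontal axis, normalised count plus 1) of the AC3-/- mean over the wild-type mean, over wild-type library a alone and over wild-type library b alone, for each list (vertical axis) with at least 3 miRNAs with library values, whose number is in brackets. The miR-183 cluster lies at -0.11 against library a and -2.17 against library b, and the ciliated list at -0.67 and 2.23. The Dlk1-Dio3 cluster lies at 0.26 against each and at 0.21 over the wild-type mean.

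The remaining lists did not stand apart from matched random lists after adjustment in the main setting. In other settings 5 of them passed. Endothelium and smooth muscle passed with members of at least 10 normalised reads (median 0.20 in the authors' deposited table, adjusted share 0.028). camera did not call that list (adjusted p = 0.494 with a preset and 0.99 with an estimated correlation). Over its 7 miRNAs with library values the median was 0.00, and it was 0.62 without wild-type library a and -0.43 without library b. The miR-30 family passed against unmatched lists (adjusted share 0.024). Striated muscle and the p53-linked miRNAs passed without AC3-/- library a (-0.80 and 0.89, adjusted shares 0.0493 and 0.014). The ciliated list passed without wild-type library a (1.5, adjusted share 0.002) and, with the opposite sign, without library b (-0.55, adjusted share 0.016). The neuronal list as a whole had a median log2 fold change of -0.05 over 49 miRNAs in the authors' deposited table (adjusted share 0.735), with 1 called member, miR-124-3p, which is also the 1 member called when p-values are adjusted over the list alone. miR-9-5p had means of 107473 in AC3-/- and 103336 in wild type, and miR-125b-5p 23997 and 25994, in the authors' deposited table. The list linked to cAMP and neuronal activity had a median of -0.04 over 15 miRNAs (adjusted share 0.797), and its best-known member, miR-132-3p, had 494.8 and 435.1 normalised reads in AC3-/- against 445.2 and 426.8 in wild type. In the authors' deposited table the medians were -0.08 for the let-7 family (adjusted share 0.803), 0.05 for the miR-17~92 paralogs (0.71) and -0.30 for the miR-30 family (0.165). There they were -0.13 for the miR-29 family (0.735), 0.22 for the p53-linked miRNAs (0.084) and 0.23 for the 2 arms of miR-210, the hypoxia list (0.71). In the authors' deposited table miR-210-3p, with means of 502.0 in AC3-/- and 486.0 in wild type, was at 0.04. The scarce miR-210-5p, with 8.471 and 4.942, was at 0.42. Among tissue lists of the authors' deposited table the medians were 0.19 for endothelium and smooth muscle (0.0816), -0.22 for striated muscle (0.121), -0.10 for red blood cells (0.797) and -0.13 for mesenchyme and cartilage (0.706). There they were 0.01 for squamous and basal epithelium (0.735), -0.13 for liver (0.71) and -0.01 for the endocrine list (0.71). Of the 6 red blood cell miRNAs, 5 lay below 0, among them miR-486a-3p, miR-486a-5p and miR-486b-3p, which share reads. The 1 above 0 was the most abundant, miR-451a, at 0.33 in the authors' deposited table. The endocrine list had 1 member called when p-values were adjusted over the list alone, miR-7b-5p.

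miR-7b-5p had 1098.5 and 205.7 normalised reads in AC3-/- against 102.0 and 106.4 in wild type. In the authors' deposited table its log2 fold change was 1.51 with p = 0.00236 and an adjusted p of 0.9254. Its log2 ratio of means, which carries no shrinkage, was 2.63 with all libraries, 0.97 without AC3-/- library a and 3.39 without AC3-/- library b. Among lower miRNAs, none of which passed, the 5 with the smallest p in the authors' deposited table were miR-129-1-3p, miR-1191a, miR-3086-5p, miR-3083-5p and miR-3083b-3p, with log2 fold changes of -1.47, -1.17, -1.15, -1.27 and -1.27 and p from 0.00319 to 0.0101. miR-129-1-3p had 24.39 and 28.22 normalised reads in AC3-/- against 43.57 and 820.9 in wild type, so most of its difference lay in wild-type library b. miR-1191a had 43.56 and 29.13 against 81.82 and 118.1, and miR-3086-5p, in an intron of Hspa12a on chromosome 19 from 58911673 to 58911759, 29.62 and 28.22 against 61.63 and 94.72. miR-3083-5p and miR-3083b-3p had nearly the same reads in every library. Both AC3-/- libraries lay above both wild-type libraries for 75 of the 447 miRNAs and below for 76, together 33.8%, where chance gives 33.3%.

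The most abundant miRNAs of the tissue other than those above did not pass. miR-148a-3p had means of 1501741 in AC3-/- and 1301717 in wild type in the authors' deposited table (log2 fold change 0.18, adjusted p = 0.9441). miR-21a-5p, in the Vmp1 gene on chromosome 11 from 86584067 to 86584158, had 999383 and 716969 (0.28, adjusted p = 0.9395 in the authors' deposited table). The means of the authors' deposited table were 474412 and 408720 for miR-143-3p, 422172 and 526677 for miR-30a-5p, 324103 and 466344 for let-7f-5p and 267932 and 301196 for miR-26a-5p. Scaling each genotype to its total in place of the authors' size factors would add 0.50 to every log2 fold change. This turns the sign of 10 lists, the let-7 and miR-30 families among them, and leaves the miR-183 cluster at -0.40 and the miR-200 family at -0.05. The last 2 lists largely set that shift themselves. Their summed means were 818741 in AC3-/- and 2716673 in wild type for the miR-183 cluster, and 1013889 and 2746825 for the miR-200 family. This difference is about as large as the gap between the totals, 8739148 and 12320877, so total scaling is no independent check on them.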

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

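The limma, camera and fry tests, the replicate blocks, the leave-one-out fits on recovered libraries and the scaling to totals were chosen after seeing the data. The call of 1 miRNA in the authors' deposited table held at adjusted p thresholds of 0.01 and 0.1, with a log2 fold change of at least 1, with the adjustment over miRNAs of at least 10 or 100, with Bonferroni adjustment and with the more abundant arm per precursor. An unadjusted p under 0.05 gave 41; limma on the recovered libraries called 0, also with no minimum and after quantile normalisation, and leaving out 1 library gave 0 to 65, the 65 without wild-type library a. The 41 of 1167 became 29 of 492 with a mean of at least 10, 17 of 296 with a mean of at least 100 and 26 with a log2 fold change of at least 1. limma gave 18 of 447 miRNAs with a mean of at least 10, 17 after quantile normalisation, 42 of 1122 with no minimum, and 2 to 128 of 447 with 1 library left out. For miR-124-3p the log2 value of 2.26 became 2.77 with a pseudocount of 1, 2.75 with total scaling, 2.81 with limma and 2.43 to 3.21 with 1 library left out; these values carry none of the shrinkage of the deposited one, but for total scaling. The 4 lists that stood apart became 2 with members of at least 100, 1 with the more abundant arm per precursor (leukocyte) and 0 over miRNAs with library values. With members of at least 10 normalised reads 4 lists passed, 3 of them the same. With 1 library left out 1 to 3 lists passed, of which 0 or 1 was among the 4; the others were the ciliated, striated muscle and p53 lists. On the recovered libraries camera called 2 lists with a preset correlation and 0 with an estimated one, and fry, which does not compare a list with other miRNAs, called 0. With 1 library left out the miR-200 median ranged from -0.80 to 0.22 and the leukocyte median from -0.02 to 1.63, the sign turning without wild-type library b in both. Beyond the fewer miRNAs or libraries that some of these settings use, the cause was not tested. The recovered libraries carry no replicate number, so which of their 2 possible pairings follows the numbers is not known. As a replicate block in limma, pairing the libraries a, and so the libraries b, called 1 miRNA, miR-124-3p (adjusted p = 0.00846; 27 at an unadjusted p under 0.05), and pairing a with b called 0 (adjusted p = 0.212; 24). camera with a preset correlation called 3 and 5 lists, the miR-183 cluster, ciliated and leukocyte lists in both. The deviations of paired libraries correlated at -0.19 with the libraries a paired, the pairing that called miR-124-3p. With a paired with b the value is 0.19 by construction, so the 2 are 1 measurement. The 2 other splits of the 4 libraries into 2 against 2 gave 6 and 30 miRNAs at an unadjusted p under 0.05 in limma, against 18 for the genotypes, and called 0; they are too few for a share under 0.05. Count models with other size factors were not run. Depth limits the rows under a mean of 10, which hold 12 of the 41.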

Other observations

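The tests in this part were chosen only after the results were seen. Of the miRNAs outside the rule, those given here were chosen after their values were seen, and none passed the adjusted p in the authors' deposited table. miR-1298-5p, from an intron of the serotonin receptor gene Htr2c on the X chromosome, had 446.0 and 381.4 normalised reads against 240.1 and 146.2 (p = 0.0134 and adjusted p = 0.9395 in the authors' deposited table). miR-18a-5p, of the proliferation-linked miR-17~92 cluster, had 219.5 and 307.7 against 122.2 and 148.5, while its list did not move. miR-489-3p lay lower, with 17.42 and 14.56 against 38.25 and 39.76. miR-129-5p had 138.1 normalised reads in wild-type library a and 1537.8 in library b, with 222.1 and 126.5 in AC3-/-.

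The lower miR-183 cluster and miR-200 family in AC3-/- may follow from what wild-type library b holds. Over the 7 of their 16 miRNAs with library values and a mean of at least 10, the median log2 ratio of AC3-/- was 0.20 to wild-type library a and -1.45 to library b. A wrong size factor is argued against, since the median log2 ratio of library b to a lay 1.29 higher for these miRNAs than for all 447, a difference that no single factor changes. 99.7% of random sets of 7 miRNAs lay below it. That share is no added support, because these lists were picked for a difference that rested on library b, and their members move together. An even dilution of library a relative to library b by other tissue, ciliated lining included, is also argued against. The medians of 7 lists of other tissues lay up to 3.29 apart, more than 2 times the largest SD within a list, 1.30. This rests on the ciliated list: over the other 6 the gap was 2.15, under 2 times 1.30, with striated muscle at 0.36, so a dilution by those tissues stays open. A candidate explanation is that library b came from a piece with less ciliated airway lining than library a. The ciliated miRNAs prompted this and so do not test it. Their median log2 ratio of the AC3-/- mean was -0.67 to wild-type library a and 2.23 to library b, so library b lay further from AC3-/-. In the AC3-/- pair the ciliated miRNAs were higher in library b, with a median log2 ratio to library a of 0.85 over 6. There the 7 miRNAs had a median of -0.46, less than their SD of 0.57 from 0, with 4 lower and 3 higher. Split by list, the median was -0.82 over the 3 of the miR-183 cluster and 0.12 over the 4 of the miR-200 family. A difference in ciliated lining and other differences between the libraries cannot be told apart on these values. How many of these miRNAs olfactory cells also make is not known. An effect of genotype on the cluster stays open, as untested, because the most abundant members have no library values.

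For the higher miR-124-3p, the difference did not rest on 1 outlying library, since the lower AC3-/- library lay 4.89-fold above the higher wild-type library. The miRNA was picked by its p in these same libraries, so this describes them and is no separate test. Brain tissue, such as olfactory bulb, carried along in the AC3-/- samples could also raise miR-124-3p. Over 9 miRNAs of a list of brain miRNAs with a wild-type mean of at most 100, written before the test but with some values already seen, the median log2 fold change was 0.09 in the authors' deposited table and 2 were at 0.5 or more, the most abundant being miR-344-3p at 138.2 in AC3-/- and 64.14 in wild type. Brain tissue and a change in the epithelium cannot be told apart here, because the list's members went both ways and the level each would need is not known. A change of miR-124-3p in olfactory neurons stays a hypothesis.

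For the slightly higher Dlk1-Dio3 list, the lowest median log2 ratio with 1 library left out was 0.06, without AC3-/- library a, against an SD between libraries of 0.11 over 78 miRNAs. Over the 43 with a mean of at least 10 the lowest was 0.12, against an SD of 0.03. Both lowest values leave out AC3-/- library a, which leans the ratio downward where libraries vary. The 78 miRNAs do not clear their spread and the 43 do. A shift set by 1 library and a shift of the genotype are therefore not told apart. The cluster lies on the same chromosome as Adcy3, with miR-381 at 109726822 and Adcy3 ending at 4213525; no biological explanation was tested.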
